A study of Mus musculus with 2 samples.

How the data were processed

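The data are 2 RNA sequencing libraries of mouse hindlimb skeletal muscle at postnatal day 30 on the C57BL/6 background, 1 WT and 1 SRSF1-MKO. Per the labels' protocols, total RNA was taken with Trizol and libraries were made by a Lifetech procedure. The number of animals behind each library, their sex, and the strandedness of the libraries are not given in the sources used here.

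The authors deposited 1 table of FPKM values (fragments or reads per kilobase of transcript per 1000000 mapped reads) with 1 column per genotype, and the unit is taken from the name of that table and from its values. The submitters' processing notes name Bowtie and the mouse genome build mm10; the version of the aligner, the gene annotation and the counting method are not given in the sources used here. No log or filter had been applied to the deposited FPKM values, since exact zeros were kept. The FPKM sums were 462919 for WT and 575130 for SRSF1-MKO, so the columns are not scaled to a common sum. In the table, 1 line had been emptied before use and is not analysed here. Every column of per-sample values was used.

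Columns were given to genotypes by the genotype in their names. Each sample's 2 description lines disagree: the first line of the WT sample names the KO column and the second names the WT column, and the reverse holds for the SRSF1-MKO sample. The column names match the genotype of the second lines, and the level of Srsf1 was reported but not used for this choice. Column and genotype labels were therefore taken at the level of the group, and the direction of each difference holds under this reading of the labels.

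Of 44787 gene rows, 32096 symbols matched the RefSeq gene table directly, 1824 were matched through the Entrez number in the table, and 10867 kept the deposited name. In 27 rows a spreadsheet had turned the symbol into a date. Rows that shared a symbol (4 rows) were summed. Gene coordinates, exon-union lengths and GC content came from GENCODE release M21 (GRCm38, the assembly that mm10 names).

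Whole reads leave a step in FPKM, because each gene's value is a whole multiple of the value of 1 read. Of 19044 genes above 0 in both libraries, 92.8% had a ratio between libraries that was a fraction of whole numbers times 1 constant (denominators to 3000, relative tolerance 1e-12), against 0.294% when the constant was changed by 1 part in 10000. The constant, 1.08, is the FPKM of 1 read in SRSF1-MKO over that in WT. Library totals followed from 1109 genes with low counts whose exon-union length was within 30% of their genomic span; 256 of them gave the commonest total, 23.1 M reads for WT (M for 1000000), which implies 21.4 M for SRSF1-MKO. These totals are the divisor the authors used, as far as the values show it. Approximate reads per gene were FPKM times this total times the exon-union length, and the authors' own gene lengths may differ.

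Each gene was compared as log2((SRSF1-MKO FPKM + 1)/(WT FPKM + 1)), with a pseudocount of 1, among the 10478 genes with a mean of 1 FPKM or more, of which 9468 are typed mRNA. With 1 library per group there is no test between genotypes. Genes were counted at a log2 ratio of 1 or more in size (2-fold). For named genes, the ratio of FPKM is given with an exact (Clopper-Pearson) binomial 95% interval on the approximate reads. Such intervals, and the floor of 3 reads for genes listed at 0, cover counting error only: they hold no variation between animals or library preparations.

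The 23 gene lists and 12 marker lists, the counting rules and the rule for named genes were fixed before the data were examined. For each list the median log2 ratio of members with a mean of 1 FPKM or more was set against 10000 random lists of the same size, drawn with replacement from genes in the same of 20 bins of mean expression. A list was said to stand apart when its median lay outside the middle 95% of these random medians; lists with fewer than 4 measured members, and the sex-linked list, had no percentile. The percentile describes these libraries and ignores that members of 1 pathway are expressed together. Muscle as a tissue also expresses many of the marker genes: at 1 FPKM or more in WT stood 11 of 16 macrophage, 11 of 12 adipocyte, 12 of 12 endothelial, 12 of 13 fibro-adipogenic, 6 of 10 erythroid, 6 of 8 smooth muscle, 7 of 12 Schwann cell and 8 of 11 tendon genes, and 0 of the marker genes stand on another list. Members were counted as higher or lower at 1.5-fold on the log2(FPKM + 1) scale, and counted again after the median of 0.32 over the 4991 genes with a mean of 5 FPKM or more was taken off. Genes named in the text are Srsf1, the 12 with the largest and the 12 with the smallest log2 ratio at a mean of 5 FPKM or more (predicted genes, clone names and small RNAs left out), up to 4 members of each list with the largest ratios, all measured neuromuscular junction members, list members wherever a count was 5 or fewer (a few of these members are not reported here), and the 5 most abundant genes of each library. The few other genes named, Acta1, Pax7, Pcna, Mdm2, S100a9, Casq1, Atp2a1 and Uty, were chosen after their values were seen.

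The most abundant genes took a similar part of both columns: the 5 highest made up 26.1% of the FPKM sum in WT (the 18S ribosomal RNA row, Myh4, mt-Co1, Tnnc2 and Myl1) and 23.0% in SRSF1-MKO (mt-Co2, the 18S ribosomal RNA row, mt-Co1, mt-Nd1 and mt-Atp6).

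The procedure was tested on simulated data for the same comparison, with reads drawn at the recovered depths for 10507 genes of which 200 had known changes. Apart from the known changes, both simulated libraries had the same base levels and held counting error only. Variation between animals or preparations, a length trend and an overall shift were not simulated. The rates that follow therefore do not give error rates for the real comparison. The 2-fold rule took 22 unchanged genes. At a true 3-fold change it took 96% of genes made higher and 85.7% of those made lower, and at 4-fold 100% and 95.5%; at a true 2-fold change it took 8% and 12%, since the pseudocount shrinks low ratios. Of 200 unchanged lists, 6.5% lay outside the middle 95% of random lists. These unchanged lists were random draws themselves, so a low rate was set by construction. Of 20 lists of 12 genes raised by 1.5-fold, 100% lay above that middle 95%. All 20 were drawn from 1 shared set of raised genes, so they overlap and are not independent trials.

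Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter, a mean of 5 FPKM or more, the all-gene median set to 0, rescaling to a sum of 1000000, scaling to the percentile 75 of genes above 0, a total without the 20 most abundant and the mitochondrially encoded genes, and the highest row per symbol. After the data were seen, 4 were added: mRNA rows only, the median of genes of like exon length taken off (20 bins), the same for GC content, and lists without members found on another list. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.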

Results

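RNA was measured by sequencing in hindlimb skeletal muscle of C57BL/6 mice at postnatal day 30, with 1 wild-type (WT) library and 1 library labelled SRSF1-MKO. SRSF1 is a serine/arginine-rich protein that binds exonic RNA and takes part in splice site choice. The labels do not spell out the abbreviation MKO, and the question taken from them is how the muscle transcriptome of this genotype differs from that of WT. The deposited FPKM table covers 44787 gene rows, of which 20717 were above 0 in the WT library and 21895 in the SRSF1-MKO library. The library totals recovered from the FPKM values were 23.1 M reads for WT and 21.4 M for SRSF1-MKO (M for 1000000), so that 1 FPKM on a transcript of 1 kb stands for about 23.1 and 21.4 reads. A mean of 1 FPKM or more was reached by 10478 genes. Each group holds 1 library, so no difference reported here has a replicate check, no test between genotypes was made, and the intervals given cover the counting of reads only.

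The targeted gene was lower in the library labelled SRSF1-MKO. Srsf1 (ENSMUSG00000018379.17, GRCm38 chromosome 11, 88047373 to 88053755, plus strand) was at 13.7 FPKM in WT and 6.70 FPKM in SRSF1-MKO, a ratio of 0.489 with an exact binomial 95% interval of 0.450 to 0.532. On the log2(FPKM + 1) scale the difference was -0.93, and -1.25 once the all-gene median was set to 0. About 1810 and 817 reads stood behind these values, which are 1 sum per gene and do not separate exons. The deposited table places the gene on an alternate scaffold of the assembly, and the coordinates above are those of the GENCODE annotation. Whether reads were split between the scaffold and the chromosome copy is not given in the sources used here, so the levels and read numbers may cover only part of the transcript's reads. The submitters' 2 description lines for each sample contradict each other about which table column belongs to which sample, and the columns were taken by the genotype in their names; the direction of every difference below rests on that.

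Several sarcomere genes of slow and embryonic muscle were among the genes with the largest ratios in the SRSF1-MKO library, and the fast-fibre genes Mybpc2 and Actn3 were among those with the smallest. At the fixed size rule, 989 genes were at least 2-fold higher and 327 at least 2-fold lower in SRSF1-MKO on the log2(FPKM + 1) scale, which understates the ratio of genes with low FPKM. The higher genes made up 75.2% of this set. This split depended on the scaling: the median log2 ratio was 0.21 over genes with a mean of 1 FPKM or more and 0.32 over genes with a mean of 5 or more, and with the second median set to 0 the counts were 537 higher and 659 lower, or 44.9% higher. Differences of 8-fold or more were found in 59 genes on the higher side and 14 on the lower side. Across genes, which are not independent replicates, the log2 values of the 2 libraries had a Spearman rho of 0.870.

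Among genes with a mean of 5 FPKM or more, the 12 with the largest log2 ratio were Csrp3, Ankrd2, Myl4, Myh3, Sln, Myl3, Myl2, Myoz2, Tnni1, Tnnc1, Mt2 and Fhl1. Csrp3, which encodes a LIM protein of the Z-disc (chromosome 7, 48830398 to 48848033), was at 1.32 FPKM in WT and 252 in SRSF1-MKO, 191-fold higher with a 95% counting interval of 153 to 239. Ankrd2, an ankyrin repeat protein of muscle, went from 7.23 to 471 FPKM between the libraries, a ratio of 65.1 (56.6 to 75.8). Myh3, the embryonic myosin heavy chain, was at 0.817 and 89.2 FPKM, and Myl4, a light chain of embryonic muscle and atrium, at 3.42 and 234 FPKM. Sarcolipin (Sln), a small inhibitor of the sarcoplasmic calcium pump, was at 1.83 and 120 FPKM. The remaining members of the 12 had log2 ratios between 4.97 for Fhl1 and 5.39 for Myl3. Myl3 was covered by few reads in WT, at 0.0962 FPKM, and its ratio had the wide interval of 182 to 1310.

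The 12 genes with the smallest log2 ratio were Eif2s3y, Mybpc2, Fos, Map2k6, Ddx3y, Plcd4, Mettl21c, Ky, Fosb, Actc1, Actn3 and Car3. Mybpc2, the fast-type myosin-binding protein C (chromosome 7, 44501699 to 44524656), was 14.1-fold lower, at 1419 FPKM in WT and 101 in SRSF1-MKO. Actn3, the alpha-actinin of fast glycolytic fibres, was 7.39-fold lower, at 2851 and 386 FPKM. Map2k6, a kinase upstream of p38, was at 23.3 and 0.775 FPKM, and Plcd4, a phospholipase C, at 33.5 and 2.09 FPKM. Mettl21c, a muscle methyltransferase, was at 10.1 and 0.0806 FPKM. Carbonic anhydrase 3 (Car3) was at 164 and 21.8 FPKM, and Ky, a Z-disc-associated peptidase-like protein, at 70.8 and 6.64 FPKM. Actc1, the cardiac actin, was at 2313 and 279 FPKM; it shares long stretches with the skeletal actin Acta1 (13109 and 10040 FPKM), so its level is uncertain where reads were split between both. Eif2s3y and Ddx3y lie on the Y chromosome and are described with the other sex-linked genes.

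**Figure D1:**
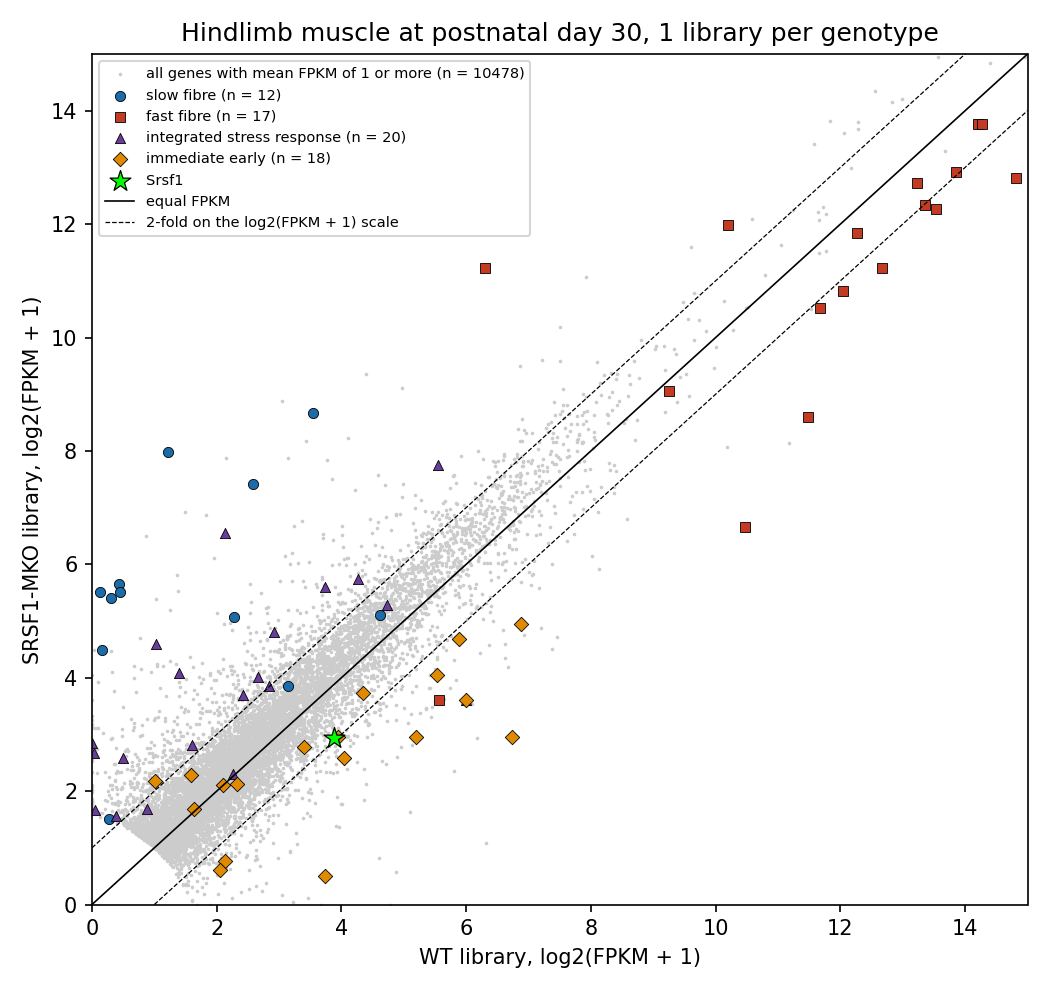
Each grey point is 1 of 10478 genes, with log2(FPKM + 1) in the WT library on the x axis and in the SRSF1-MKO library on the y axis; the solid line marks equal FPKM and the dashed lines a 2-fold difference on this scale. Slow-fibre genes (circles, 12) lie above the solid line, with a median log2 ratio of 4.94, most immediate early genes (diamonds, 18) below it, with a median of -1.29, and Srsf1 (star) at -0.93.

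Slow-fibre genes formed the list with the highest median of all 31 lists ranked. Of 12 measured members, 11 were at least 1.5-fold higher in SRSF1-MKO and 0 were lower, with a median log2 ratio of 4.94 (percentile 100 among 10000 random lists matched on mean expression, whose median was 0.35). A list is said to stand apart when its median lies outside the middle 95% of such random lists. Myl2, the slow regulatory light chain, was at 0.345 FPKM in WT and 49.5 in SRSF1-MKO; slow troponin I (Tnni1) was at 0.235 and 41.3 FPKM, and slow troponin C (Tnnc1) at 0.369 and 44.5 FPKM. Myoz2, the calsarcin of slow and cardiac muscle, was at 10.6 and 404 FPKM. Tpm3 was the member under 1.5-fold, at 23.5 and 33.6 FPKM. Only 6 of the 12 members reached 1 FPKM in WT, so several of the large ratios start from very low WT values. In the SRSF1-MKO library several slow isoforms stayed far below fast ones. Myh7, the slow myosin heavy chain, was at 21.6 FPKM there beside Myh4 at 7176, and Tnnc1 at 44.5 beside Tnnc2 at 13997.

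Fast-fibre genes were lower as a list, with 10 of 17 members at least 1.5-fold lower and a median log2 ratio of -1.03 (percentile 0, random median 0.51). Besides Mybpc2 and Actn3, the list held Myh4, the myosin heavy chain of the fastest fibres (type 2B; chromosome 11, 67238029 to 67260446), which was 4.01-fold lower at 28777 FPKM in WT and 7176 in SRSF1-MKO. The fast myosins themselves went apart. Myh2, the heavy chain of type 2A fibres, was 30.7-fold higher (78.2 and 2399 FPKM, interval 30.2 to 31.2), and Myh1, that of type 2X fibres, was at 1176 and 4028 FPKM. The 5 members between the limits, Mylpf, Myl1, Tnni2, Tnnc2 and Myoz1, had log2 ratios between -0.50 and -0.19. The neighbouring Myh genes are close in sequence, so single values in this cluster carry the uncertainty of shared reads.

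Genes of excitation-contraction coupling, which link the depolarised membrane to calcium release, were lower as a list. Of 16 members, 8 were at least 1.5-fold lower and 3 higher, and the median log2 ratio was -0.76 (percentile 0, random median 0.48). The ryanodine receptor Ryr1 was 4.74-fold lower, at 280 FPKM in WT and 59.1 in SRSF1-MKO. The junctional protein Jph2 was at 143 and 46.7 FPKM, and Cacna1s, the voltage sensor of the transverse tubule, at 131 and 48.9 FPKM. Cacng1 (76.4 and 231 FPKM), Mtm1 (2.60 and 5.04 FPKM) and Bin1 (263 and 396 FPKM) were higher. Of these members, 2 also stand on the fast-fibre list, Casq1 and Atp2a1. Genes of the dystrophin complex did not stand apart (14 members, median log2 ratio 0.12, percentile 13.75): 0 were lower, and higher members included Cav3 (22.8 and 99.3 FPKM) and Utrn (4.08 and 6.84 FPKM). Relative to the all-gene median, 1 member was higher and 2 were lower.

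Energy metabolism differed by pathway. Glycolysis and glycogen genes were lower relative to random lists (18 members, median log2 ratio -0.08, percentile 0.19, random median 0.47), although 11 of the 18 were within 1.5-fold. Lower members included Phkg1 (120 and 25.9 FPKM), the glycogen phosphorylase Pygm (1158 and 269 FPKM), Pgam2 (2941 and 1448 FPKM) and Eno3 (760 and 502 FPKM). The 2 higher members were hexokinase 2 (Hk2, 36.3 and 78.2 FPKM) and the insulin-responsive glucose transporter Slc2a4 (34.2 and 60.9 FPKM). Fatty acid oxidation genes did not reach the limit (20 members, median log2 ratio 0.67, percentile 95.84), with 12 members higher and 1, Acads, lower at 9.22 and 3.97 FPKM. Within that list Pdk4, the kinase that shuts off pyruvate dehydrogenase, was 18.3-fold higher (16.3 and 299 FPKM), and Fabp3, the heart-type fatty acid-binding protein, 6.40-fold higher (181 and 1158 FPKM). Ucp3 was at 20.1 and 69.5 FPKM.

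The 13 mRNAs encoded by mitochondrial DNA were higher as a list, with 9 at least 1.5-fold higher and 0 lower (median log2 ratio 1.23, percentile 99.9). Their share of reads was 8.31% in WT and 16.2% in SRSF1-MKO. The largest log2 ratios were those of mt-Nd3 (776 and 3088 FPKM), mt-Nd1 (6041 and 20939 FPKM) and mt-Cytb (4992 and 14189 FPKM), while mt-Co1, mt-Co3, mt-Nd5 and mt-Nd4l were the 4 members within 1.5-fold. The 2 mitochondrial ribosomal RNAs took 0.835% and 3.11% of reads, and the 18S ribosomal RNA row 5.87% and 5.85%. Nuclear genes of oxidative phosphorylation did not stand apart: 16 of 31 were at least 1.5-fold higher and 0 lower, but the median log2 ratio of 0.60 lay at percentile 78.43 among lists of like expression, and 6 members were higher relative to the all-gene median. Cox5b (186 and 449 FPKM) and Sdhd (56.6 and 133 FPKM) had the largest ratios in this list.

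Genes of the neuromuscular junction, the synapse between motor nerve and fibre, were higher as a list. Of 20 measured members, 12 were at least 1.5-fold higher and 2 lower, with a median log2 ratio of 0.69 (percentile 99.96, random median 0.20); relative to the all-gene median the counts were 6 and 5. Acetylcholine receptor subunits were among the higher members. Chrne was 7.17-fold higher (4.81 and 34.5 FPKM, interval 6.15 to 8.41), Chrnd 9.61-fold (0.714 and 6.86 FPKM), Chrna1 4.72-fold (3.72 and 17.6 FPKM) and Chrnb1 2.62-fold (15.02 and 39.3 FPKM). The receptor kinase Musk was at 0.989 and 6.01 FPKM, and Colq, the collagen tail of acetylcholinesterase, at 0.655 and 4.53 FPKM. Erbb3, Dok7, Etv5, Nes, Hdac4 and Utrn were higher by log2 ratios between 0.62 and 0.89. The sodium channel Scn4a (32.9 and 15.5 FPKM) and Ptprs (3.29 and 1.66 FPKM) were lower. Lama5, Rapsn, Ache, Ufsp1, Agrn and Lamb2 were within 1.5-fold, and the signs of Rapsn (0.23) and Ache (0.06) changed with the scaling. The counting intervals of both ratios, 0.975 to 1.53 for Rapsn and 0.920 to 1.21 for Ache, included 1.

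The denervation response list, genes known to be higher in muscle that has lost its nerve, had 14 of 15 members at least 1.5-fold higher and a median log2 ratio of 2.44 (percentile 100, random median 0.32). Besides Myh3 and Sln, the cell cycle inhibitor Cdkn1a was 35.2-fold higher (1.56 and 54.9 FPKM) and the metallothionein Mt1 18.2-fold higher (30.3 and 553 FPKM). Ky was the 1 lower member. Of these 15 genes, 9 also stand on other lists used here, among them Chrna1 and Hdac4. The embryonic and neonatal list had 10 of 15 members higher and 1, Actc1, lower (median log2 ratio 0.79, percentile 99.4). It held Myl4, Myh3 and Tnnt2, the cardiac troponin T of fetal muscle, which was 12.1-fold higher at 8.41 and 102 FPKM. Cdh15, H19, Peg3 and Myod1 were its 4 members within 1.5-fold.

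Satellite cell and myoblast genes did not stand apart (16 members, median log2 ratio 0.05, percentile 20.37). The 3 members higher by 1.5-fold were the Notch target Hes1 (4.35 and 15.7 FPKM), Itga7 (7.16 and 20.6 FPKM) and Sdc4 (13.7 and 33.9 FPKM), which are not restricted to satellite cells. Pax7, the marker of the satellite cell itself, was under the filter at 0.604 and 0.550 FPKM. Cell cycle genes were lower relative to random lists (14 members, median log2 ratio -0.34, percentile 0.08), all at low FPKM apart from Pcna (12.001 and 13.6 FPKM). Aurka (2.81 and 0.910 FPKM), Mki67 (4.23 and 1.92 FPKM), Ccnd1 (7.08 and 3.76 FPKM) and Tpx2 (2.35 and 1.22 FPKM) were the 4 lower members, and Rrm2 (1.25 and 2.94 FPKM) the 1 higher.

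Genes of the integrated stress response, which are driven by ATF4 when translation initiation is restrained, were higher in the SRSF1-MKO library. Of 20 measured members, 17 were at least 1.5-fold higher, with a median log2 ratio of 1.55 (percentile 100, random median 0.25). Mthfd2, the mitochondrial one-carbon enzyme, was 27.4-fold higher (3.41 and 93.3 FPKM, interval 24.3 to 31.0), and asparagine synthetase (Asns) 22.4-fold higher (1.04 and 23.3 FPKM, interval 17.4 to 29.0). Psat1, of serine synthesis, was at 1.62 and 15.9 FPKM. The hormone gene Fgf21 was listed at 0 in WT, where 3 reads would give 0.136 FPKM, and was at 6.23 FPKM in SRSF1-MKO. Atf3 was the 1 lower member (63.1 and 11.1 FPKM) and also stands on the immediate early list. Endoplasmic reticulum stress genes did not stand apart (14 members, median log2 ratio 0.00, percentile 3.75); Herpud1 alone passed 1.5-fold, at 23.8 and 51.1 FPKM, and the chaperone Hyou1 was at 4.30 and 3.37 FPKM. Macrophage markers, described with the other cell types, were higher in the same library.

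Heat shock genes did not stand apart (12 members, median log2 ratio 0.47, percentile 63.82). The small heat shock proteins Hspb7 (9.79 and 288 FPKM, 29.4-fold) and Cryab (180 and 764 FPKM), with Hspe1, Hsp90aa1 and Bag3, were the 5 higher members, and Dnajb1 (4.9996 and 1.88 FPKM) and Hsph1 (38.3 and 19.9 FPKM) the 2 lower. Genes known as p53 targets were higher as a list (13 members, 8 higher and 2 lower, median log2 ratio 0.92, percentile 99.89). Apart from Cdkn1a, which the denervation list shares, Eda2r was 17.5-fold higher (0.919 and 16.1 FPKM), Phlda3 4.25-fold (11.2 and 47.7 FPKM) and Aen 2.48-fold (10.3 and 25.6 FPKM). Ccng1 (233 and 125 FPKM) and Ddit4l (58.3 and 36.9 FPKM) were lower, and Mdm2 was at 20.8 and 19.9 FPKM.

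Atrophy and autophagy genes were higher as a list, with 10 of 20 members at least 1.5-fold higher and a median log2 ratio of 0.65 (percentile 98.79, random median 0.31). The ubiquitin ligase Fbxo32 was 6.16-fold higher (5.95 and 36.6 FPKM), the translation repressor Eif4ebp1 6.42-fold (10.1 and 65.1 FPKM) and the autophagosome protein Map1lc3a 4.08-fold (28.2 and 115 FPKM). Mstn, the secreted inhibitor of muscle growth, was the 1 lower member, 5.46-fold lower at 25.1 and 4.60 FPKM.

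Immediate early genes, which respond within minutes to activity and handling, had the lowest median of the 31 lists ranked. Of 18 members, 13 were at least 1.5-fold lower in SRSF1-MKO, with a median log2 ratio of -1.29 (percentile 0, random median 0.25). Fos was 15.6-fold lower (105 and 6.74 FPKM), Fosb 29.7-fold (12.3 and 0.413 FPKM), Atf3 5.67-fold and Egr1 5.26-fold (35.8 and 6.80 FPKM). Maff (1.01 and 3.52 FPKM) and Ier3 (2.02 and 3.86 FPKM) were higher. The circadian clock list did not stand apart (16 members, median log2 ratio -0.02, percentile 5.77). Its 5 lower members were Per3 (5.86 and 2.04 FPKM), Dbp (55.5 and 25.3 FPKM), Hlf (2.81 and 1.07 FPKM), Bhlhe41 (8.23 and 4.15 FPKM) and Nr1d2 (29.8 and 19.3 FPKM). Interferon response genes were lower relative to random lists (15 members, median log2 ratio -0.33, percentile 0.14), with Isg15 lower past 1.5-fold (1.71 and 0.743 FPKM) and Rsad2 higher at 0.947 and 3.06 FPKM.

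Other splicing factors did not stand apart from random lists. Of 32 members, 9 were at least 1.5-fold higher and 3 lower, with a median log2 ratio of 0.20 (percentile 12.71, random median 0.33), and relative to the all-gene median the counts were 3 and 5. The largest values were those of Hnrnph1 (78.8 and 38.7 FPKM, 2.03-fold lower), Tra2b (19.7 and 39.2 FPKM, 1.99-fold higher), Hnrnpc (22.4 and 43.8 FPKM) and Srsf11 (26.2 and 50.4 FPKM). Hnrnpa2b1 (285 and 163 FPKM) and Rbfox1 (33.4 and 21.8 FPKM) were the other lower members. These are gene-level values, and exon use was not analysed here.

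Extracellular matrix genes were lower relative to random lists (27 members, median log2 ratio -0.25, percentile 0, random median 0.29), and the members went both ways. Col1a1 (276 and 121 FPKM), Col1a2 (135 and 65.9 FPKM), Col15a1 (23.6 and 9.98 FPKM) and Sparc (232 and 154 FPKM) were the 4 lower members. Osteopontin (Spp1) was 44.3-fold higher (0.285 and 12.6 FPKM, interval 24.2 to 88.3), Timp1 16.8-fold (1.07 and 17.9 FPKM), Col8a1 5.44-fold (2.08 and 11.3 FPKM) and periostin (Postn) 4.13-fold (28.3 and 117 FPKM); Ccn2 and Bgn completed the 6 higher members. Relative to the all-gene median, 13 members were lower and 5 higher.

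Markers of other cell types moved apart from each other. Macrophage markers were higher, with 9 of 14 measured members at least 1.5-fold higher and 0 lower (median log2 ratio 0.87, percentile 100, random median 0.19): Ctss was 7.94-fold higher (5.56 and 44.2 FPKM), Cd68 10.6-fold (0.752 and 7.99 FPKM), Lyz2 3.10-fold (18.1 and 56.3 FPKM) and Fcer1g 3.29-fold (1.84 and 6.05 FPKM). Adipocyte markers were lower (10 members, 7 lower and 0 higher, median log2 ratio -0.87, percentile 0), among them Scd1 (28.6 and 5.08 FPKM) and adiponectin (Adipoq, 9.36 and 2.66 FPKM). Endothelial markers were lower relative to random lists (12 members, median log2 ratio -0.28, percentile 0.23), with Cdh5 (17.0 and 9.03 FPKM) and Kdr (9.23 and 5.24 FPKM) past 1.5-fold. Relative to the all-gene median, 6 endothelial members were lower and 0 higher. Tendon and cartilage markers were lower as a list (8 members, median log2 ratio -0.60, percentile 0.01) but split: Kera (10.9 and 2.46 FPKM), Fmod (25.3 and 10.3 FPKM), Col11a1 and Tnmd were lower, whereas the tendon transcription factor Scx (1.67 and 13.3 FPKM) and Thbs4 (34.6 and 105 FPKM) were higher.

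Erythroid markers were lower relative to random lists (6 members, median log2 ratio -0.36, percentile 1.26), with 0 members past 1.5-fold. Relative to the all-gene median, 4 were lower. Hbb-bs was at 96.9 and 72.5 FPKM, and the globin copies share reads. Markers of fibro-adipogenic progenitors and fibroblasts did not stand apart (12 members, median log2 ratio 0.12, percentile 12.85), with Mfap5 higher (5.60 and 11.97 FPKM) and Cd34 lower (12.4 and 7.90 FPKM). Neither did those of smooth muscle and pericytes (7 members, median log2 ratio 0.23, percentile 47.99, 0 past 1.5-fold, 2 lower relative to the all-gene median). Nor did those of Schwann cells and myelin (7 members, median log2 ratio 0.47, percentile 90.17), of which Pmp22 was higher (10.2 and 17.7 FPKM). T and B cell markers had 0 measured members. The neutrophil list had 1, S100a8, listed at 0 in WT and at 15.5 FPKM in SRSF1-MKO, while its partner S100a9 was at 0.247 and 0.0894 FPKM. The keratinocyte list had 1, Sfn, at 0.643 and 2.29 FPKM.

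**Figure D2:**
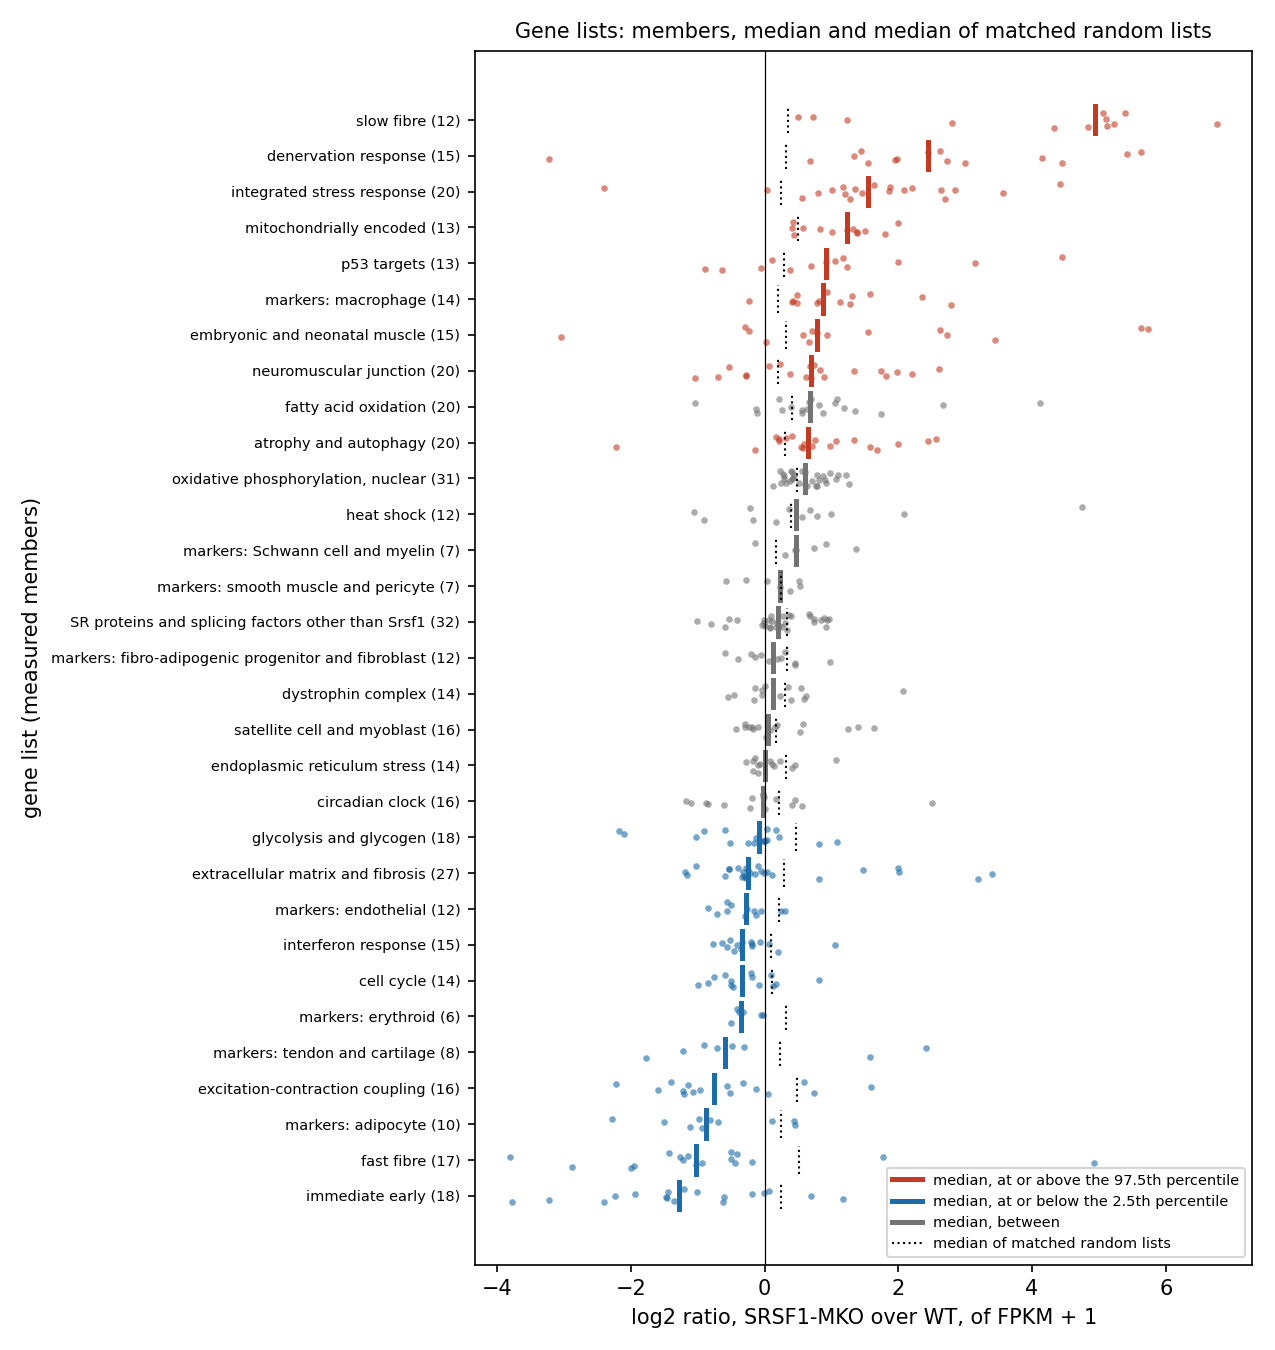
Log2 ratios of FPKM + 1, SRSF1-MKO over WT, for the 31 lists with a percentile; points are measured members, thick bars list medians and dotted bars the median of matched random lists. Medians of 9 lists (red) lay above and those of 11 lists (blue) below the middle 95% of random lists, from 4.94 for slow-fibre genes to -1.29 for immediate early genes, and 11 lists (grey) lay between.

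The libraries also differed in sex-linked transcripts, and the labels give no sex. Xist, the RNA of the inactive X chromosome, was at 0.00482 FPKM in WT and 8.15 in SRSF1-MKO. The Y-linked genes Eif2s3y (26.5 FPKM), Ddx3y (11.7), Kdm5d (2.20) and Uty (1.77) were seen in WT and were listed at 0 in SRSF1-MKO, where 3 reads would give 0.0338 FPKM for Eif2s3y and 0.0270 FPKM for Ddx3y. X-linked genes as a group had a median log2 ratio of 0.19 (322 genes), against 0.20 for autosomal genes (9780 genes). These values point to male tissue in the WT library and female tissue in the SRSF1-MKO library. Genotype and sex then differed between the same 2 libraries, so every difference above is between libraries that differ in both. Of the 20 lists that stood apart, 15 did so in each alternative run, while the neuromuscular junction, embryonic and neonatal, atrophy and autophagy, p53 and erythroid lists lost that position in at least 1 alternative.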

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

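No paired analysis was possible because each group has 1 library. Of the 20 lists that stood apart, 15 did so under all alternatives, 9 of them planned and 4 chosen after seeing the data. The slow-fibre median stayed between 3.18 and 5.91 and the integrated stress response median between 0.92 and 1.97, both at percentile 100, and the fast-fibre median between -1.35 and -0.94 and the immediate early median between -1.61 and -0.65, both at percentile 0. Every other scaling moved the median ratio down, so lower genes could hardly leave their set; of the 989 higher genes, 537 stayed at least 2-fold higher with the median set to 0. Which scaling is right cannot be settled without spike-ins or replicates, and depth limits genes with few reads, such as Myl3 in WT. The cause was not tested for the values that follow, except that a high pseudocount shrinks ratios and a filter leaves fewer genes by construction.

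With the pseudocount at 0.1, 1399 genes were higher and 533 lower. At 5, Srsf1 was at -0.68, 446 genes were higher and 120 lower, and the medians were 0.46 for atrophy (percentile 97.43) and 0.39 for p53 targets (91.97). With a mean of 5 FPKM or more, 633 were higher and 201 lower. The neuromuscular junction (0.66, percentile 92.88), embryonic (0.68, 87.82) and erythroid (-0.20, 4.77) lists no longer stood apart. The satellite cell list stood apart under this filter (1.25, 99.75), but its median was the value of Sdc4, which is not restricted to satellite cells. With the all-gene median set to 0, Srsf1 was at -1.25, 537 genes were higher and 659 lower, Rapsn was at -0.087 and Ache at -0.26. Rescaled to a sum of 1000000, Srsf1 was at -1.21, with 584 higher and 564 lower, Rapsn at -0.016 and Ache at -0.19. Upper-quartile scaling put Ache at -0.12. Without the 20 most abundant and the mitochondrial genes, Srsf1 was at -1.21, with 593 higher and 558 lower, Rapsn at -0.012 and Ache at -0.19. Of the alternatives added later, the length correction gave 606 higher and 513 lower, Rapsn at -0.13, Ache at -0.035 and Creld2 at -0.00084, and fatty acid oxidation stood apart (0.51, percentile 99.2). The GC correction gave Srsf1 at -1.18, 505 lower genes and Ache at -0.14. Without members shared between lists, the embryonic (0.74, percentile 92.4) and atrophy (0.58, 96.46) lists no longer stood apart.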

Other observations

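The genes and groups in this paragraph and the next were chosen after their values were seen. Stretch-related proteins of the Z-disc and sarcomere went apart: of 10 measured ankyrin repeat, LIM and Xin genes, 6 were at least 1.5-fold higher in the SRSF1-MKO library and 3 lower. Ankrd1, a partner of titin, was 18.03-fold higher (12.7 FPKM in WT and 228 in SRSF1-MKO), next to Csrp3 and Ankrd2, whereas its relative Ankrd23 (330 and 164 FPKM) and the Xin genes Xirp2 (330 and 153 FPKM) and Xirp1 (41.0 and 24.7 FPKM) were lower. Myoglobin (Mb) was at 242 and 2135 FPKM and the M-band protein Myom3 at 1.05 and 40.7 FPKM. The simple-epithelial keratins Krt18 (0.0246 and 21.5 FPKM) and Krt8 (0.0718 and 14.2 FPKM), which pair with each other, were nearly absent from WT. All 3 measured metallothioneins were higher, Mt3 among them at 0.723 and 16.9 FPKM, though such short related genes share reads.

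Genes of translation gave no clear result as groups. Of 18 cytosolic aminoacyl-tRNA synthetases, 10 were at least 1.5-fold higher and 0 lower, and the median log2 ratio of 0.66 lay at percentile 96.97, inside the middle 95%, and at 99.42, outside it, with the length trend taken off; Gars (24.1 and 77.9 FPKM) and Sars (20.8 and 66.9 FPKM) had the largest ratios. Of 72 cytosolic ribosomal protein genes, 41 were higher and 0 lower (median 0.69, percentile 99.63, random median 0.46). These are short genes, and with the length trend taken off their percentile was 96.64, inside the middle 95%. That trend runs through the whole table: median log2 ratios fell from 0.43 for the shortest 20% of genes by exon length to 0.10 for the longest 20%. Serine and one-carbon genes as a group did not stand apart (9 measured, median 0.07, percentile 25.96); cytosolic Mthfd1 (13.8 and 5.99 FPKM) was lower and mitochondrial Mthfd2 higher. S100a8 was at 15.5 FPKM in SRSF1-MKO without its usual partner S100a9 (0.0894 FPKM).

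In what follows, the length and GC tests were written down before their results were seen, and all other tests were chosen only after the result was seen. The first pattern is that slow-fibre genes were higher and fast-fibre genes lower. Their medians differed by 5.98, and by 5.92 with the length trend and 5.94 with the GC trend taken off, in 29 of 29 members. Across the table, median log2 ratios ran only from 0.43 for the shortest genes to 0.10 for the longest. By GC content they ran from 0.23 for the lowest to 0.18 for the highest. Taking off trends this small could hardly close such a gap, so the outcome was set beforehand. The values show only that both trends are small beside the gap. Reads shared between fast and slow paralogs would make slow genes follow their fast paralogs; the slow-fibre median of 4.94 restates the pattern and decides nothing, but Tnnc1 at 0.369 FPKM in WT and 44.5 in SRSF1-MKO, beside Tnnc2 at 19837 and 13997, argues against sharing as the whole cause. A different mix of hindlimb muscles remains open: Myh7, the slow myosin, was at 21.6 FPKM against 0.121 in WT, and a share of slow muscle in 1 dissection might give such values. The biological alternative, a fibre-type difference that comes with the genotype, may hold as well, and 1 library per group does not separate it from dissection.

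The second pattern is the higher integrated stress response. With the length trend taken off, the list median was 1.19 instead of 1.55, still at percentile 100. The length trend across the table is small beside 1.55, so taking it off could hardly have removed the pattern. The correction shows only the size of that trend and is not counted as a test of length. Endoplasmic reticulum stress as the source would likely raise chaperones such as Hyou1, but that list lay at percentile 3.75. A part played by macrophages stays open: Lyz2, abundant in macrophages, was 38.2 FPKM higher and Atf4 169 FPKM higher, but Asns reached only 23.3 FPKM, and no macrophage profile was at hand. A mitochondrial origin that comes with the genotype is possible, as mitochondrial mRNAs were higher too, but no test of it was run. Of 12 mitochondrial chaperone and protease genes, a group chosen after the data were seen, 7 were at least 1.5-fold higher and 1 lower. Their median log2 ratio of 0.75 lay at percentile 96.94, and at 94.85 with the length trend taken off. Both lie inside the middle 95%, so this group does not decide the question.

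The third pattern is the difference in sex-linked transcripts. Eif2s3y was at 26.5 FPKM in WT and 0 in SRSF1-MKO, and Xist at 0.00482 and 8.15 FPKM. Together these values point to male tissue in the WT library and female tissue in the SRSF1-MKO library, although the labels hold no sex. Genotype and sex then differ between the same 2 libraries, so the part of each difference owed to sex cannot be told apart from genotype. Exchanged column labels would put the higher Srsf1 value in the mutant, whereas the ratio was 0.489 with an upper counting bound of 0.532, which argues against an exchange if the mutation lowers the transcript.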
